A study of Caenorhabditis elegans with 6 samples.

How the data were processed

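The data are gene-level tables from paired-end RNA sequencing of total RNA from whole bodies of *Caenorhabditis elegans* hermaphrodites of the wild-type strain N2, collected between the last larval stage (L4) and the prefertile adult stage at 20 °C. There were 6 libraries in 2 groups of 3: worms under control RNAi and worms under combined RNAi of rnk-1 and rnk-2. In feeding RNAi, worms eat bacteria that express double-stranded RNA matching a target gene. Per the labels' protocols, the bacteria for rnk-1 and for rnk-2 were grown separately at 37 °C with 100 µg/mL ampicillin to an optical density of 0.9 at 600 nm and mixed in a 1:1 ratio. RNA was extracted with RNAiso plus and sequenced on a NovaSeq 6000, per the labels' protocols. The labels name HT115 bacteria as food in the growth protocol and OP50 bacteria in the extraction protocol, so the food is uncertain. Groups and replicate numbers come from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

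The deposited tables hold 46904 genes per library, with WormBase gene identifiers. Per the file headers, the authors' estimated counts are RSEM expected counts, which are not normalized and need not be whole because a read shared between genes is split among them. TPM, per the file headers, is the authors' relative transcript abundance after correction for effective length; rrn-2.1, a ribosomal RNA gene, holds 69.0 to 87.8% of it. The deposited effective length of each gene, and the deposited posterior standard deviation of its count, which is above 0 where reads are shared with another gene, were used as well. The submitters' processing notes name TopHat2 2.1.0, Bowtie 0.12.9, RSEM 1.3.1 and DESeq2 1.28.1 with the builds WBcel235 and ce11. The role of each tool, the annotation release, the strand setting and the library kit were not given in the sources used here. Without a strand setting, reads from overlapping genes on opposite strands cannot be told apart; 15 of the 47 genes named by rule overlap another annotated gene.

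Expected counts were rounded to whole numbers. Totals were 45233413, 50884727 and 55303944 counts in control replicates 1 to 3 and 50883654, 53528324 and 54268214 in RNAi replicates 1 to 3. Genes were kept by the filterByExpr function of edgeR with its minimum count of 10, which left 16561 genes, and libraries were scaled by the trimmed mean of M values (TMM). The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on all 6 libraries with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called changed at an adjusted p under 0.05. The SE of a log2 fold change was derived from its quasi-likelihood F statistic. Levels are TMM-scaled CPM (counts relative to the scaled library total), given as mean ± SD over 3 libraries. For a gene with no count in the control group, the fold is a lower bound against a floor of 3 counts over the group, and for a gene with 1 to 3 control counts it is a ratio of counts with an exact 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Measures of single libraries were compared by 2-sided exact permutation tests, which with 3 against 3 libraries cannot give a p below 0.1.

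Before the data were examined, 44 gene lists were fixed, and gene classes were defined as symbol prefixes with at least 10 tested members, which gave 152 classes. Lists and classes were tested with the camera function of limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation between genes of 0.01, and adjusted within each family. Camera with a correlation estimated from the data, and fry, a rotation test, were run beside it. Camera compares a list with the other genes, whereas fry asks whether the members of the list changed at all. The numbers of their calls therefore answer different questions. The symbols fixed for the mitochondrially encoded list are spelled differently in the tables, so its members were taken as the 12 protein-coding genes of the mitochondrial chromosome. List members were also counted with p-values adjusted over the list alone. List medians are given relative to the median of all tested genes. After the results were seen, medians of lists past camera were also set against 10000 random lists of genes from outside the list, each member replaced by 1 of its 20 nearest genes in rank of length and expression. A fit with a measure of stage, the sperm minus the early embryo list median of each library, as a covariate was run as well; it extrapolates, since the groups do not overlap in that measure.

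The genes named were set by a rule fixed at the same time: the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 1 CPM and no overlap between groups; the 2 members with the smallest p in each of the 6 lists with the smallest p; the member with the smallest p in 7 lists close to the subject of the study; and 2 members of each of the 6 leading classes. The member that the rule named in the stress granule list is not reported here. Genes outside the rule are said to have been chosen after their values were seen. The rule also named rnk-1 and rnk-2, but these symbols matched 0 genes in the symbol table, the annotation (WBcel235) and the RefSeq table used here. The level of the RNAi targets is therefore not analysed here, and the group labels were not checked by it. Symbols were found for 45961 of the 46904 identifiers. Circular RNA, which the series title names, is not measured by gene tables.

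Alternatives fixed in advance were size factors from DESeq2 1.42.0, upper-quartile factors, library size only, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries), the DESeq2 Wald test, limma-voom, limma on log2(TPM + 1) and on log2(TPM + 0.1) for genes above 1 TPM in 3 libraries, effective-length offsets, removal of the 50 most abundant genes, robust dispersion, the replicate number as a block, each library left out in turn, and, for lists and classes, camera on ranks, camera with an estimated correlation and fry. Removal of ribosomal RNA and mitochondrial genes, and the edgeR test glmTreat against a 2-fold change, were chosen after seeing the data. Pairs of libraries within a group differed by a chi-square of 69.3 to 295 per degree of freedom over genes, so no pair held the same counts within counting error, which does not show that they are separate cultures.

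The procedure was tested on simulated counts for the control against RNAi comparison, drawn from the control means and the real library sizes and gene-wise dispersions, with 200 changed genes. Of the simulated genes, 15386 passed the filter. The test called 0% of 1.5-fold, 11.9% of 2-fold and 59.1% of 4-fold changes in the right direction at adjusted p, and 55.2%, 79.1% and 93.9% at an unadjusted p under 0.05, with 3 unchanged genes called. In the data 8860 of 16561 genes changed, which makes the adjustment less strict there, so the shares at adjusted p do not carry over to the real comparison. The median ratio of estimated to true log2 change was 1.17, 1.04 and 0.989 for the same sizes. When the intracellular pathogen response list alone was raised 2-fold, camera called it (adjusted p = 1.07e-31) and 0 other lists. The simulated genes were drawn independently of each other, whereas members of real lists varied together, with an estimated correlation of 0.52 for cytosolic ribosomal proteins. The simulation therefore does not show how often camera calls unchanged lists in these data. The plots were drawn with matplotlib 3.10.9.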

Results

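RNA from whole worms was sequenced after control RNAi (3 libraries) and after combined RNAi of rnk-1 and rnk-2 (3 libraries), with a total of 45233413 to 55303944 expected counts per library. The series title names ribonuclease κ, longevity, circular RNA and stress granules as the subject, and the comparison asks which linear transcripts differed at gene level between the 2 groups. The RNAi libraries held more genes with at least 1 count (19829 ± 210 against 18663 ± 175, SD, n = 3 each). Nuclear ribosomal RNA made up 3.81% ± 2.19 of counts under rnk-1 rnk-2 RNAi and 10.24% ± 1.74 in the controls, and mitochondrial mRNA 1.32% ± 0.470 and 2.15% ± 0.245. For each of these 3 measures the libraries of the groups did not overlap, with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. Mitochondrial ribosomal RNA made up 11.7% ± 3.65 and 14.1% ± 3.93 of counts (exact permutation p of 0.6). The first principal component, which held 80.05% of the variance of log2 CPM, separated the groups, and the next held 9.75%. The RNAi targets rnk-1 and rnk-2 were matched to no gene identifier, so their levels are not analysed here and do not check the group labels.

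Under rnk-1 rnk-2 RNAi, 36 of 47 measured genes of the intracellular pathogen response rose, as did 26 of 41 epidermal antimicrobial peptide genes, 122 of 208 nuclear hormone receptor genes and 23 of 41 neuronal genes. Genes that fell included 80 of 85 for cytosolic ribosomal proteins, 45 of 56 of the spliceosome, and 41 of 48 for oxidative phosphorylation. Others that fell were 36 of 40 oocyte genes, 39 of 49 germline genes, 55 of 76 histone genes and 4 of 6 vitellogenin (yolk protein) genes. These are calls of single genes. As lists, all of these passed camera with a preset correlation and none did with an estimated correlation (adjusted p = 0.429 to adjusted p = 0.665). The members of the pathogen response list had a median log2 fold change of 2.29 relative to all genes, and the ribosomal protein and oocyte lists had medians of −0.99 and −1.02. These 3 medians were 0.70, −0.31 and −0.43 on log2(TPM + 1), over the 9503 genes kept on that scale and relative to their median. A cluster of 6 pud genes on chromosome V held 6 of the 10 largest falls.

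Of 16561 genes tested, 8860 (53.5%) changed at an adjusted p under 0.05 in the quasi-likelihood test of edgeR, 4972 of them higher and 3888 lower under RNAi. The expression ranges of the groups did not overlap for 11240 genes (67.9%), against 10% by chance. Among the changed genes, 4186 were at least 2-fold higher and 1271 at least 2-fold lower, and 387 and 37 differed by at least 16-fold in the same directions. Changed genes with no count in any control library numbered 33, and 0 changed genes had no count in any RNAi library. At an unadjusted p under 0.05, 10206 genes differed, and DESeq2 and limma-voom called 9709 and 9543. The median log2 fold change of all tested genes was 0.14 on the TMM scale. The fold changes of single genes are on that scale, and medians of lists and classes are relative to the median of all genes. The split depended on the scaling: with library size only it was 7134 higher and 984 lower, and on log2(TPM + 1) and log2(TPM + 0.1) 7095 and 7156 were higher and 120 and 132 lower. On these TPM scales, 18 named genes that fell with TMM had log2 differences above 0. Without control replicate 2, 5713 genes changed, 3132 higher and 2581 lower.

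**Figure D1:**
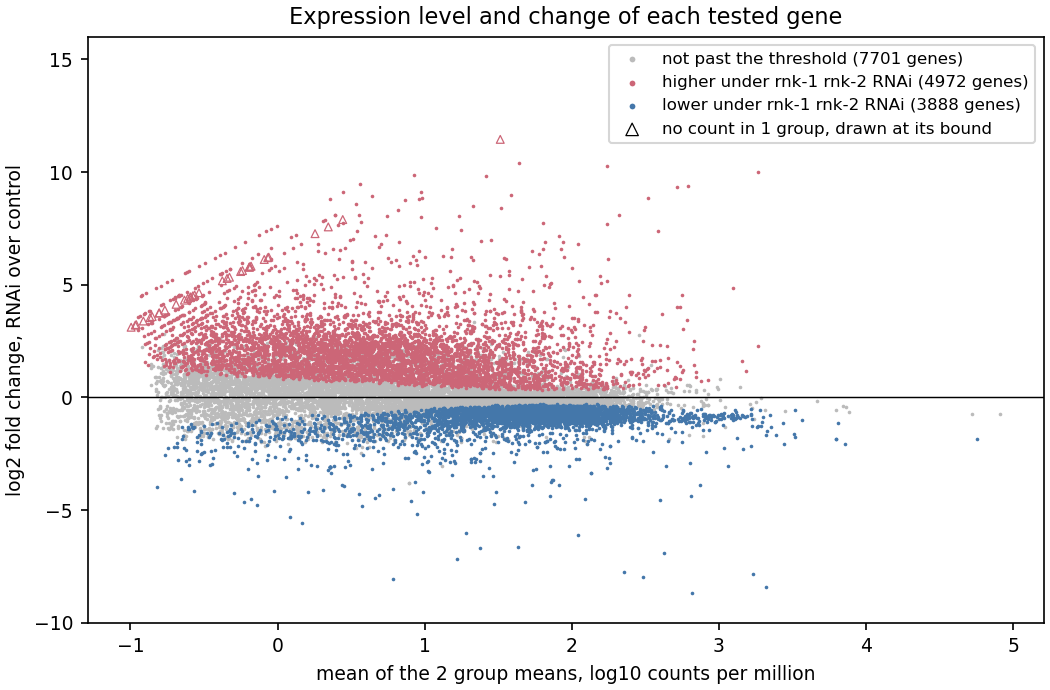
Log2 fold change (rnk-1 rnk-2 RNAi minus control RNAi) of each of the 16561 tested genes against the mean of the 2 group means (log10 CPM), coloured by whether the gene was higher, lower or not past an adjusted p of 0.05. Open triangles mark genes with no count in 1 group, drawn at their bound; 4186 changed genes lay at least 2-fold up and 1271 at least 2-fold down.

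The largest rises by the rule for named genes included several on chromosome II (positions on build WBcel235). F22E5.6 (WBGene00017705, protein-coding, II 2649835 to 2650813) had no count in the 3 control libraries and 65.3 ± 4.61 CPM under RNAi, at least 2793-fold higher (adjusted p = 4.05e-05). The chemoreceptor gene sri-36 (WBGene00005548, II 2583732 to 2585593), the pseudogene R07C3.16 (WBGene00269338, II 919575 to 920407) and F57G4.1 (WBGene00010206, V 17623530 to 17624559) also had no control count and were at least 154-, 237- and 189-fold higher. The rule ranked by fitted log2 fold change, which was 10.56, 11.19 and 10.86 for these genes and lies above their bounds. Their places among the largest rises therefore rest on the fit. F33H12.7 (WBGene00045457, II 2586078 to 2586911) lies beside sri-36 and rose from 0.285 to 348 CPM (log2 fold change 10.26 ± 0.32 SE; adjusted p = 2.23e-05). On the same chromosome sdz-35 (WBGene00022570, II 3207683 to 3208779) rose from 0.0611 to 87.2 CPM (10.40 ± 0.43). Y41C4A.32 (WBGene00270321, III 11721706 to 11723607) rose from 3.62 to 3706 CPM (SE of the log2 fold change 0.50) and spp-27 (WBGene00271815, V 6556653 to 6557135), of the saposin-like protein family, from 0.0551 to 52.2 CPM (9.84 ± 0.33). Both overlap an annotated gene on the opposite strand, so their reads may be shared with it. The insulin-like gene ins-20 (WBGene00002103, II 6010844 to 6011321) had 2 control counts and a count ratio of 1082 (95% counting interval 299 to 8939). The antimicrobial peptide gene cnc-1 (WBGene00000555, V 1444044 to 1444280) had 1 control count and a ratio of 921 (165 to 36385). On log2(TPM + 1), which understates changes of low genes, F22E5.6, sdz-35, ins-20, spp-27 and cnc-1 rose by 4.76, 4.70, 3.89, 5.61 and 6.05. Outside the rule, chosen after their values were seen, the genes with the smallest p were warf-1 (WBGene00000190, IV 7634786 to 7635712), which rose from 1.59 to 1031 CPM (9.34 ± 0.25), and Y37H2A.14 (WBGene00045416, V 18143745 to 18144720), which rose from 1.42 to 662 CPM (8.87 ± 0.25).

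The pud genes, first described as encoding proteins raised in daf-2 mutants, lie between V 2322038 and 2330930. Of these, pud-3 (WBGene00017501, V 2324634 to 2325152) fell from 1304 to 3.16 CPM (log2 fold change −8.69 ± 0.56 SE; adjusted p = 9.66e-05) and pud-4 (WBGene00017498, V 2326678 to 2327282) from 451 to 2.104 CPM (−7.75 ± 0.59). Their neighbours pud-1.1, pud-1.2, pud-2.1 and pud-2.2 had log2 fold changes of −7.97 ± 0.38, −7.84 ± 0.54, −6.90 ± 2.00 and −8.39 ± 1.74. These 4 share reads with near-identical copies and are uncertain one by one; pud-2.1 lost its call without control replicate 2 (−7.17), without RNAi replicate 2 (−6.35) and with glmTreat, with adjusted p up to 0.0767, and its value without RNAi replicate 1 was −13.10. The cuticle collagen gene col-43 (WBGene00000620, V 8049703 to 8050911) fell from 12.17 to 0.0450 CPM (−8.05 ± 1.01). The short-chain dehydrogenase gene dhs-26 (WBGene00000989, X 3360722 to 3362493) fell from 32.7 to 0.224 CPM (−7.19 ± 0.38). Y48E1B.8 (WBGene00013007, II 13585705 to 13589038) and the acid sphingomyelinase gene asm-3 (WBGene00000213, IV 520214 to 523809) had log2 fold changes of −6.68 ± 0.45 and −6.64 ± 0.61. On log2(TPM + 1) dhs-26, Y48E1B.8 and asm-3, which overlap genes on the opposite strand, fell by 1.65, 1.89 and 2.02.

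**Figure D2:**
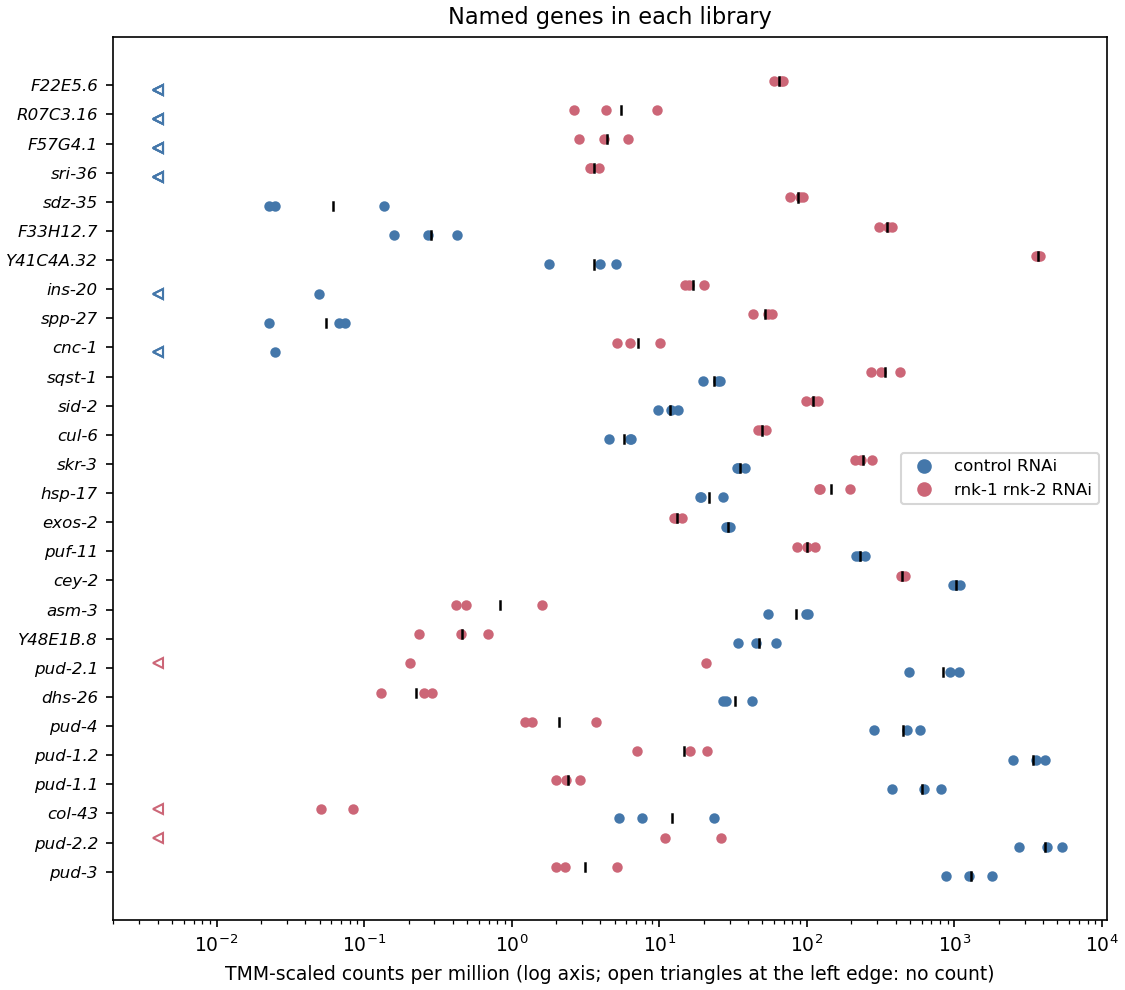
TMM-scaled CPM of named genes in each of the 6 libraries on a log axis, coloured by group, with black ticks at group means and open triangles at the left edge for libraries with no count. In pud-3 the group means were 1304 and 3.16 CPM, and in Y41C4A.32 3.62 and 3706 CPM.

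Of the 44 gene lists, 23 passed camera with the preset correlation, 5 higher and 18 lower under RNAi. With a correlation estimated from the data, camera called 0 lists, with 2 at an unadjusted p under 0.05, while fry called 29. On the other ways of splitting the 6 libraries 3 against 3, camera with the preset correlation called 16 to 25 lists. Those splits mix the groups unequally, so part of the group difference remains and these counts are no rate of false calls. On log2(TPM + 1) and log2(TPM + 0.1), 18 and 20 lists passed. These scales kept only the 9503 genes above 1 TPM in 3 libraries. List members and the median of all genes there can therefore differ from those of the main test, and not the scale alone. Ranges of adjusted p given for lists cover the settings other than the estimated correlation. Because camera called 0 lists with an estimated correlation, list calls are given as descriptions of these libraries, beside counts of changed members from the gene tests. Directions are relative to the median of all genes. Without that reference, 3 of the 18 lower lists had a median above 0 with library size only, 16 on log2(TPM + 1) and 15 on log2(TPM + 0.1).

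In the intracellular pathogen response, a set of genes induced by microsporidia and virus infection, 36 of 47 measured members rose and 1 fell (37 and 1 adjusted over the list alone). The one that fell, sdz-6 (−4.52), was chosen after its values were seen. The relative median was 2.29, or 0.70 on log2(TPM + 1) over the genes kept on that scale and relative to their median. Its camera adjusted p = 1.75e-10, and adjusted p = 0.429 with an estimated correlation. The ubiquitin ligase genes skr-3 (WBGene00004809, V 16121084 to 16122649) and cul-6 (WBGene00000841, IV 12586485 to 12590451) rose from 35.2 to 241 CPM (log2 fold change 2.77 ± 0.14 SE) and from 5.80 to 49.4 CPM (3.09 ± 0.18). Of the pals genes, many of which belong to this response, 18 of 25 rose and 0 fell (relative median 2.24; camera adjusted p = 4.67e-06, and adjusted p = 0.713 with an estimated correlation). Of 41 epidermal antimicrobial peptide genes, 26 rose and 1 fell, with the same counts adjusted over the list alone (relative median 2.13; camera adjusted p = 1.51e-05, and adjusted p = 0.630 with an estimated correlation). Without the low-count filter this median was 1.403. Among them, chosen after their values were seen, nlp-24 was the one that fell (−1.98), and nlp-29 and nlp-34 rose by 5.18 ± 0.41 and 7.14 ± 0.61 on the log2 scale.

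Of 208 nuclear hormone receptor genes, 122 rose and 11 fell (124 and 11 adjusted over the list alone; relative median 0.74; camera adjusted p = 3.2e-08, and adjusted p = 0.429 with an estimated correlation). This call was lost on log2(TPM + 1), at a relative median of 0.28 (adjusted p = 0.392, range 2.59e-10 to 0.392). Lists from outside it matched on length and expression had an unshifted median of 0.57, against 0.88 for the receptors (percentile 99.8). Of 41 neuronal genes, 23 rose and 0 fell (24 and 0 adjusted over the list alone; relative median 0.74; camera adjusted p = 9.37e-05, and adjusted p = 0.665 with an estimated correlation), and the median was 1.23 on log2(TPM + 0.1). Of 102 sperm genes, 37 rose and 2 fell (27 and 2 adjusted over the list alone; relative median 1.09; camera adjusted p = 2.86e-05, and adjusted p = 0.815 with an estimated correlation). The groups overlapped for the sperm list, with medians of 1.39, 0.09 and −1.45 in control replicates 1 to 3 and 2.16, 1.63 and 1.00 in RNAi replicates 1 to 3. Without control replicate 1 the relative median of the sperm list was 1.95, and without control replicate 3 it was 0.60. It was not called by fry (adjusted p = 0.0959, range 3.49e-15 to 0.0959). The sperm list median minus the early embryo list median, a measure of stage, was 1.80, 0.09 and −1.83 in control replicates 1 to 3 and 4.83, 2.51 and 2.04 in RNAi replicates 1 to 3. With this measure as a covariate, the relative median was 0.44 for the neuronal list, 1.29 for the epidermal antimicrobial peptides, −0.65 for the histones and −0.85 for the mitochondrially encoded genes. The sperm and early embryo lists, which define the measure, then had −0.32 (adjusted p = 0.556) and −0.58 (adjusted p = 0.119). The neuronal list median minus the intestine list median was 0.437 ± 0.0729 per library under RNAi and 0.0228 ± 0.187 in the controls (SD, n = 3; exact permutation p of 0.1, the smallest possible).

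Oocyte and maternal genes were lower: 36 of 40 fell and 0 rose, with the same counts adjusted over the list alone (relative median −1.02; camera adjusted p = 1.53e-10, and adjusted p = 0.553 with an estimated correlation). The Y-box RNA-binding protein gene cey-2 (WBGene00000473, I 5619569 to 5620669) fell from 1030 to 445 CPM (log2 fold change −1.21 ± 0.13 SE) and the Pumilio-family gene puf-11 (WBGene00022257, IV 6421585 to 6423497) from 231 to 100.2 CPM (−1.203 ± 0.14). In the list for germline proliferation, meiosis and P granules, 39 of 49 fell and 0 rose (43 and 0 adjusted over the list alone; relative median −0.83; camera adjusted p = 3.4e-10, and adjusted p = 0.429 with an estimated correlation). The polo-like kinase gene plk-1 and the P granule gene deps-1 fell by 1.06 ± 0.13 and 1.13 ± 0.14 on the log2 scale. The oocyte, germline and early embryo medians were −0.43, −0.36 and −0.96 on log2(TPM + 1). Of 21 early zygotic embryo genes, 11 fell and 0 rose (12 and 0 adjusted over the list alone; relative median −1.58; camera adjusted p = 0.000442, and adjusted p = 0.668 with an estimated correlation). The early embryo list was not called by fry (adjusted p = 0.0798, range 1.73e-06 to 0.0798). Of 76 histone genes, 55 fell and 3 rose (61 and 4 adjusted over the list alone; relative median −1.90; camera adjusted p = 1.04e-08, and adjusted p = 0.630 with an estimated correlation). The his-68 gene fell by 1.79 ± 0.20 on the log2 scale, and his-61, which shares reads with other histone genes, by 1.57 ± 0.19. Both lost the call on the TPM scales, with −0.26 and −0.05 on log2(TPM + 1) (adjusted p = 0.473, range 4.79e-12 to 0.473, and adjusted p = 0.902, range 2.69e-11 to 0.902). RNAi replicate 1 stood apart, with an early embryo median of −2.67 against −0.88 and −1.04 in RNAi replicates 2 and 3, and a histone median of −2.93 against −1.29 and −1.202. Without it the relative medians of these lists were −1.19 and −1.47. Of 35 genes for dosage compensation and chromatin, 20 fell and 0 rose, with the same counts adjusted over the list alone (relative median −0.67; camera adjusted p = 1.36e-05, and adjusted p = 0.630 with an estimated correlation). This call was lost on log2(TPM + 1), at −0.28 (adjusted p = 0.0972, range 4.03e-07 to 0.0972). Of the 6 vitellogenin genes, 4 fell and 0 rose, also adjusted over the list alone (relative median −3.28; camera adjusted p = 0.00164, and adjusted p = 0.576 with an estimated correlation). Chosen after their values were seen, vit-3 fell from 1228 to 59.5 CPM (−4.37 ± 0.19), and the members not past the test were vit-2 at 0.14 ± 0.26 and vit-6 at −0.22 ± 0.25.

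Of 85 genes for cytosolic ribosomal proteins, 80 fell and 0 rose (81 and 0 adjusted over the list alone; relative median −0.99; camera adjusted p = 8.1e-18, and adjusted p = 0.553 with an estimated correlation). The list fell no more than lists of genes from outside it, of similar length but less abundant by 0.99 on the log2 scale, with an unshifted median of −0.85 against −0.93. In it rpl-23A.2 (WBGene00004439, I 8329062 to 8329647) fell from 626 to 305 CPM (log2 fold change −1.03 ± 0.13 SE), and rpl-37.2, which shares reads with another gene, from 86.1 to 43.4 CPM (−0.99 ± 0.13). Of 31 genes for the nucleolus and ribosome biogenesis, 25 fell and 0 rose, with the same counts adjusted over the list alone (relative median −0.85; camera adjusted p = 7.32e-08, and adjusted p = 0.429 with an estimated correlation). Of 41 translation factor genes, 29 fell and 0 rose (29 and 1 adjusted over the list alone; relative median −0.65; camera adjusted p = 2.1e-07, and adjusted p = 0.429 with an estimated correlation). Of 56 spliceosome genes, 45 fell and 0 rose (48 and 0 adjusted over the list alone; relative median −0.87; camera adjusted p = 5.66e-11, and adjusted p = 0.429 with an estimated correlation). The snRNP genes snr-2 and lsm-8 fell by 1.16 ± 0.12 and 1.44 ± 0.16 on the log2 scale. Of 36 proteasome genes, 26 fell and 1 rose (29 and 1 adjusted over the list alone; relative median −0.67; camera adjusted p = 1.22e-06, and adjusted p = 0.579 with an estimated correlation). The one that rose, skn-1 (0.48), chosen after its values were seen, encodes a transcription factor and not a proteasome subunit. The translation call was lost on log2(TPM + 1), at −0.10 (adjusted p = 0.382, range 1.24e-08 to 0.382). The proteasome call was lost there and on log2(TPM + 0.1), at −0.04 and −0.26 (adjusted p = 0.448 and adjusted p = 0.0611, range 1.14e-07 to 0.448). The ribosomal protein, ribosome biogenesis and spliceosome medians were −0.31, −0.36 and −0.35 on log2(TPM + 1). The translation and proteasome lists also fell no more than lists from outside them matched on length and expression, with unshifted medians of −0.51 and −0.53 against −0.49 and −0.53.

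Of 48 nuclear genes for oxidative phosphorylation, 41 fell and 0 rose (43 and 0 adjusted over the list alone; relative median −0.91; camera adjusted p = 9.52e-11, and adjusted p = 0.429 with an estimated correlation). The cytochrome c oxidase gene cox-6C (WBGene00017926, IV 126731 to 127640) fell from 111 to 45.3 CPM (log2 fold change −1.29 ± 0.13 SE), and the ATP synthase gene asg-1 (WBGene00000209, I 8692946 to 8693468) from 197 to 94.99 CPM (−1.05 ± 0.11). Of the 12 protein-coding genes of the mitochondrial chromosome, 6 fell and 0 rose, also adjusted over the list alone (relative median −1.36; camera adjusted p = 0.00133, and adjusted p = 0.630 with an estimated correlation). In the list for fatty acid beta-oxidation and propionate breakdown, 26 of 50 fell and 5 rose (29 and 5 adjusted over the list alone; relative median −0.70; camera adjusted p = 7.29e-05, and adjusted p = 0.429 with an estimated correlation). Members chosen after their values were seen went both ways: acs-2 and ech-9 rose by 5.37 and 6.08 on the log2 scale, and acox-1.2 and acdh-1 fell by 3.49 and 2.74. In the one-carbon and S-adenosylmethionine cycle, 13 of 23 genes fell and 5 rose (14 and 5 adjusted over the list alone; relative median −0.63; camera adjusted p = 0.0225, and adjusted p = 0.553 with an estimated correlation). Its median lay at percentile 17.9 of lists matched on length and expression. Both of these calls were lost on log2(TPM + 1) and log2(TPM + 0.1). The beta-oxidation medians were −0.12 and −0.27 (adjusted p = 0.252 and adjusted p = 0.151, range 8.77e-06 to 0.252) and the one-carbon medians −0.12 and −0.27 (adjusted p = 0.382 and adjusted p = 0.129, range 0.00529 to 0.382). The oxidative phosphorylation and mitochondrially encoded lists had medians of −0.32 and −0.69 on log2(TPM + 1).

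**Figure D3:**
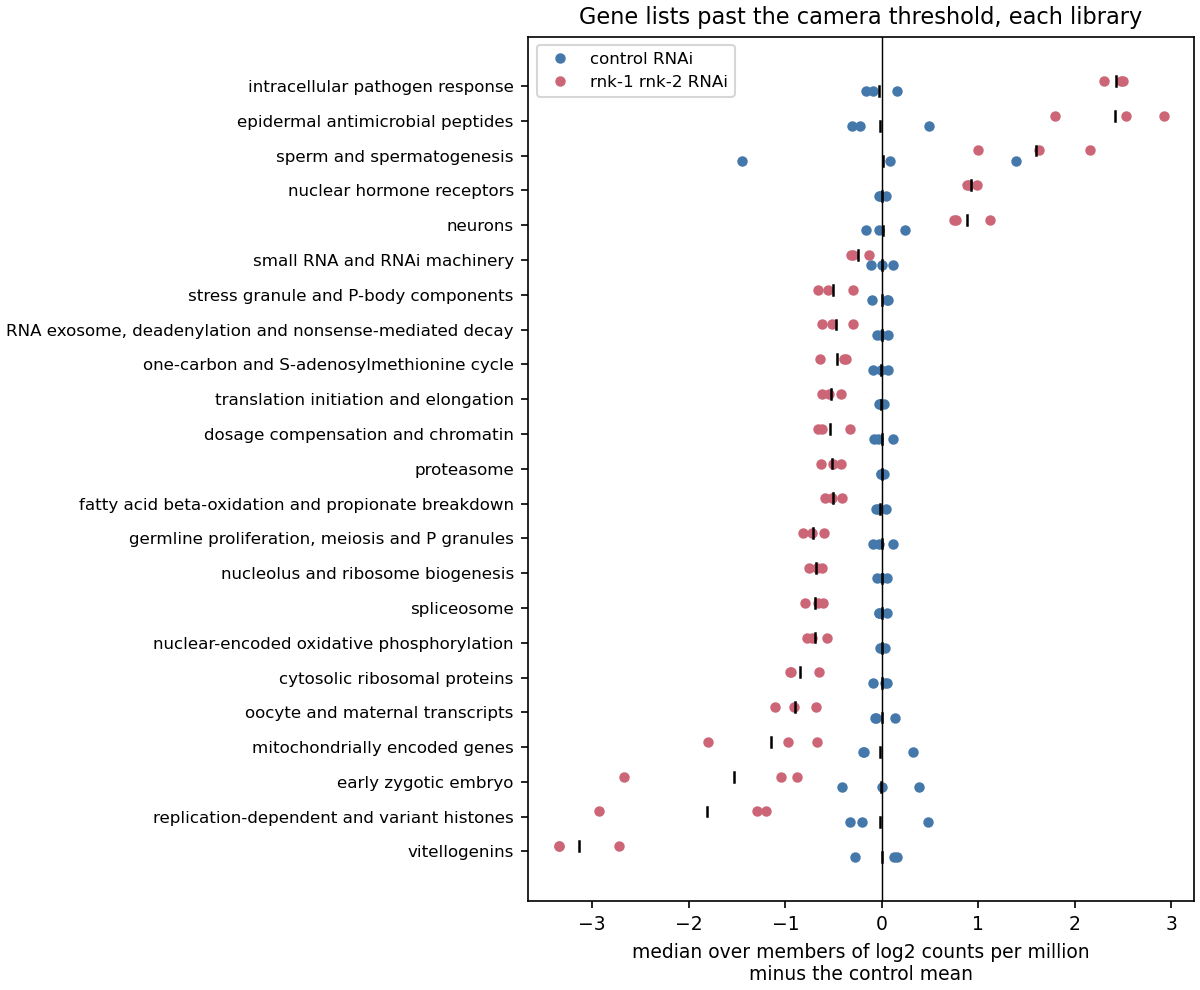
For each gene list past camera with the preset correlation, the median over members of log2 CPM minus the control mean, with 1 point per library coloured by group and a black tick at the group mean. For the oocyte list the RNAi libraries sat at −1.11, −0.91 and −0.69 and the controls at −0.07, 0.13 and −0.07.

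Among lists for RNA metabolism, 12 of 23 stress granule and P-body genes fell and 1, pab-2 (1.96, chosen after its values were seen), rose, with the same counts adjusted over the list alone (relative median −0.59; camera adjusted p = 0.00164, and adjusted p = 0.630 with an estimated correlation). Of 37 genes for the RNA exosome, deadenylation and nonsense-mediated decay, 22 fell and 1 rose, with the same counts adjusted over the list alone (relative median −0.61; camera adjusted p = 3.19e-05, and adjusted p = 0.553 with an estimated correlation). Both medians lay inside the central 95% of lists from outside them matched on length and expression, at percentile 19.3 for stress granules and 5.76 for RNA decay. Both calls were lost on log2(TPM + 1) and log2(TPM + 0.1). The stress granule medians were −0.23 and −0.29 (adjusted p = 0.269 and adjusted p = 0.129, range 0.00036 to 0.269) and the RNA decay medians −0.17 and −0.30 (adjusted p = 0.147 and adjusted p = 0.0611, range 4.54e-06 to 0.147). The exosome gene exos-2 fell by 1.14 ± 0.13 on the log2 scale. Of 44 genes of the small RNA and RNAi machinery, 17 fell and 7 rose (18 and 7 adjusted over the list alone; camera adjusted p = 0.0462, and adjusted p = 0.815 with an estimated correlation). Its relative median was −0.40, its unshifted median was −0.26 and its unshifted mean was 0.02, of opposite sign, and 10 of 21 other settings ended its call (adjusted p = 0.847 at a relative median of −0.05 on log2(TPM + 1), range 0.00847 to 0.847). Its median lay at percentile 51.6 of matched lists. The member with the smallest p, sid-2 (WBGene00004796, III 13679445 to 13682450), which encodes an intestinal protein for the uptake of double-stranded RNA, rose from 11.8 to 110 CPM (log2 fold change 3.22 ± 0.16 SE).

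Of the stress and longevity lists, none of the following passed camera. In the cytosolic heat shock response 9 of 28 genes rose and 10 fell (adjusted p = 0.707), with a mean of 0.95 and a median of −0.08 of opposite sign. The small heat shock gene hsp-17 (WBGene00002021, V 8384799 to 8385929) rose from 21.8 to 147 CPM (log2 fold change 2.75 ± 0.25 SE). In the lysosome and autophagy list 17 of 69 rose and 13 fell (adjusted p = 0.558), and the p62 orthologue sqst-1 (WBGene00011737, IV 12034282 to 12036891) rose from 23.5 to 340 CPM (3.85 ± 0.21). Of 22 V-ATPase genes 2 rose and 5 fell (adjusted p = 0.157), vha-18 falling by 0.81 ± 0.12 on the log2 scale. With library size only vha-18 lost its call, at −0.34 (adjusted p = 0.0978, range 7.56e-07 to 1.0). Of the class I targets of the insulin-pathway transcription factor DAF-16, 8 of 24 rose and 10 fell, and of its class II targets 8 of 20 rose and 5 fell. The numbers that rose and fell were 3 and 7 of 20 for the mitochondrial unfolded protein response (adjusted p = 0.0587), 10 and 2 of 27 for that of the endoplasmic reticulum, 20 and 14 of 63 for SKN-1 and glutathione detoxification, 9 and 9 of 22 for metal and RNA-splicing stress, 5 and 3 of 16 for the osmotic and glycerol response and 6 and 4 of 18 for the hypoxia response.

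Of the remaining lists, which did not pass camera either, the collagens had 64 of 149 genes higher and 22 lower (adjusted p = 0.0559), molting and apical matrix genes 12 and 1 of 42, and insulin-like peptides 12 and 1 of 26 (adjusted p = 0.0742). The PMK-1 and intestinal pathogen response list had 25 of 51 genes higher and 11 lower (adjusted p = 0.0588), and C-type lectins 52 and 25 of 134. For fatty acid desaturation and synthesis 7 of 30 genes rose and 11 fell, for cytochrome P450 29 and 18 of 73, and for UDP-glucuronosyltransferases 17 and 21 of 64. Marker genes of the intestine rose in 14 and fell in 8 of 36 cases, and those of body wall and pharyngeal muscle in 8 and 0 of 37.

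Among 152 classes of genes sharing a symbol prefix, 51 passed camera, 26 higher and 25 lower, and 0 did with an estimated correlation (6 at an unadjusted p under 0.05), while fry called 98. Mitochondrial ribosomal protein genes were among those with the smallest p: 41 of 42 mrpl genes fell (relative median −1.005; camera adjusted p = 1.43e-11, and adjusted p = 0.713 with an estimated correlation) and 27 of 29 mrps genes fell (−0.99; 9.2e-09 and 0.713). The mrpl-12, mrpl-2, mrps-35 and mrps-31 genes fell by 1.16 ± 0.11, 0.94 ± 0.11, 1.09 ± 0.11 and 1.06 ± 0.11 on the log2 scale. Cytosolic rpl genes fell in 44 of 48 cases and rps genes in 30 of 30, with rps-27 and rps-21 down by 0.85 ± 0.12 and 0.97 ± 0.14 on the log2 scale. With library size only rps-27 lost its call, at −0.38 (adjusted p = 0.0598, range 7.68e-09 to 1.0). Of the families of F-box proteins, which select targets of ubiquitin ligases, fbxa and fbxb passed camera: 95 of 162 fbxa genes rose and 11 fell (relative median 1.23), and 13 of 98 fbxb genes fell and 1 rose (−1.52). For fbxb, 0 genes passed adjusted over the class alone, and fry did not call it (adjusted p = 0.152). With an estimated correlation these had adjusted p = 0.713 (fbxa) and adjusted p = 0.718 (fbxb). The fbxc class did not pass camera, with 13 of 49 higher and 4 lower (adjusted p = 0.586). The genes fbxb-67 and fbxb-16 had log2 fold changes of −1.44 ± 0.31 and −2.76 ± 0.65, the latter overlapping fbxb-20. The genes rpl-37.2, asg-1, deps-1, sid-2, exos-2, hsp-17, vha-18, mrpl-12 and mrps-35 overlap a gene on the opposite strand and are uncertain to that extent. Not set relative to all genes, 4 of 25 lower classes had a median above 0 with library size only, and 20 of the 21 with enough genes on either TPM scale.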

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

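Of the settings reported in this part, the removal of ribosomal RNA and mitochondrial genes and the glmTreat test were chosen only after the results were seen. The number of changed genes was 8860 and lay between 7215 and 9709 in the other settings with all 6 libraries, apart from glmTreat against 2-fold, which asks for larger changes and called 1999 (1770 higher and 229 lower). DESeq2 called 9709 genes, limma-voom 9543, the stricter filter left 7879 and removal of ribosomal RNA and mitochondrial genes 8930. The share of changed genes that were higher, 56.1% with TMM, was 87.9% with library size only, which left 984 lower genes, and 98.3% and 98.2% on log2(TPM + 1) and log2(TPM + 0.1), with 120 and 132 lower. These settings moved the median log2 fold change of all genes from 0.14 to 0.61, 0.98 and 1.26. On TPM, 19 (TPM + 1) and 22 (TPM + 0.1) classes passed, with fewer genes tested. With an estimated correlation 0 lists and 0 classes passed camera, with 2 lists and 6 classes at an unadjusted p under 0.05, and fry called 98 classes.

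On log2(TPM + 1) and log2(TPM + 0.1), 18 named genes that had fallen had log2 differences above 0, none past the threshold, all below the shifted median of all genes. Among all genes, 1170 and 1223 of the 8860 calls passed in the opposite direction on these scales. The values were 0.0618 and 0.0655 for lsm-8, 0.23 and 0.24 for cox-6C, 0.28 and 0.30 for puf-11, 0.30 and 0.30 for cey-2, 0.34 and 0.35 for snr-2, 0.28 and 0.35 for exos-2, 0.33 and 0.36 for mrpl-12, 0.31 and 0.37 for mrps-35, 0.33 and 0.37 for deps-1, and 0.40 and 0.43 for plk-1. They were 0.39 and 0.44 for mrps-31, 0.47 and 0.47 for asg-1, 0.49 and 0.49 for rpl-23A.2, 0.49 and 0.57 for mrpl-2, 0.56 and 0.57 for rpl-37.2, 0.57 and 0.57 for rps-21, 0.63 and 0.69 for vha-18, and 0.69 and 0.70 for rps-27. TPM sets every gene against a total of which rrn-2.1 held up to 87.8%. Its share was 84.99, 87.79 and 82.94% in control replicates 1 to 3. In RNAi replicates 1 to 3 it was 72.44, 77.62 and 68.97%, without overlap between the groups. The lower share leaves more of the TPM total to all other genes under RNAi. Directions on the TPM scales therefore include this difference, and how much of the shift it makes up was not computed. Among lists, the cytosolic heat shock response had a median of 0.0849 on log2(TPM + 1) (adjusted p = 0.00779, range over its alternatives 0.00779 to 0.976), and the cause was not tested. The UDP-glucuronosyltransferases passed fry with the direction turned (adjusted p = 0.0317, range 0.0317 to 0.968). Their median was −0.0574 relative to all genes, the reference of camera, and 0.0822 unshifted, the reference of fry. Of the values of named genes, 908 kept direction and side of the threshold, 28 lost the call and 36 are the reversed values above; of those of lists, 880 kept both, 48 lost the call, 37 gained it and 2 reversed. Collagens gained a call in 11 settings, the PMK-1 and mitochondrial unfolded protein response lists in 7 each.

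Leaving out each library in turn gave 5713 to 8460 changed genes, 3132 to 5087 higher and 2581 to 3686 lower, 22 to 26 lists and 50 to 66 classes. The lowest counts of genes came without control replicate 2. With the replicate number as a block (the replicate block), 9443 genes changed, 5416 higher and 4027 lower, 8295 of them among the 8860, with 24 lists and 57 classes. Deviations from the group means of same-numbered libraries correlated at 0.46, −0.09 and 0.38. Control replicates 1 and 3 each correlated best with the RNAi library of the same number. Control replicate 2 correlated weakly with every RNAi library (−0.09 to 0.06). A batch shared by same-numbered libraries is therefore neither shown nor excluded. Alternatives for rnk-1 and rnk-2 were not run because the symbols matched no gene, and robust dispersion and glmTreat were not applied to lists or classes. Depth limits genes with few control counts, for which only bounds or wide counting intervals are given.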

Other observations

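The tests of length and expression for the oocyte, germline and ribosomal lists, those of the germline share, and that of the size of a background were chosen only after the results were seen, the last once the count of genes without reads had come out between its bounds. Several families not described above, picked after their values were seen, passed camera with the preset correlation. With an estimated correlation none did (adjusted p = 0.713, or adjusted p = 0.718 for spe). Of 69 nlp genes, a class of neuropeptide-like genes, 39 rose and 1 fell (median relative to all genes 0.92; camera adjusted p = 3.01e-05). The epidermal antimicrobial list holds 10 of them; of the other 59, 32 rose and 0 fell (relative median 0.85). Of the FMRFamide-like peptide genes (flp), 19 of 30 rose and 0 fell (relative median 1.004; camera adjusted p = 4.4e-05). Receptor guanylate cyclase genes (gcy) rose in 14 of 25 cases, spermatogenesis genes of the spe class in 27 of 34 with 1 falling, and genes of MATH-domain proteins (math) in 16 of 28. Nuclear pore genes (npp) fell in 18 of 26 cases with 0 rising. By chromosome, the median log2 fold change was 0.44 on V and 0.32 on X, and −0.10 on I and on III.

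Within the heat shock, collagen and RNAi machinery lists, members chosen after their values were seen went in opposite directions. Of the heat shock list, the inducible hsp-16.11 and hsp-70 rose by 3.25 ± 0.55 and 3.43 ± 0.57 on the log2 scale, whereas the constitutive chaperone genes sti-1, cct-2 and hsp-90 fell by 0.71, 0.70 and 0.56. Among collagens, rol-6, sqt-1 and dpy-5 rose by 4.80 ± 0.51, 4.64 ± 0.50 and 4.25 ± 0.58, whereas col-101 fell from 2047 to 245 CPM. Among Argonaute genes of the RNAi machinery list, sago-2 and the sperm-expressed alg-3 and alg-4 rose by 1.80, 2.504 and 2.42, and the nuclear hrde-1 and nrde-3 had log2 fold changes of −1.04 and −0.99.

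The first pattern is the fall of oocyte, germline and ribosomal protein genes. With the difference of the sperm and early embryo list medians as a covariate, 3665 genes passed for group. The oocyte median relative to all genes was then −0.89, on the side set in advance as against developmental timing along the axis from sperm to embryo. This fit cannot decide on timing, since the groups' values of that covariate do not overlap and the adjustment extrapolates. The oocyte and germline medians lay at percentile 0 of 10000 lists matched on gene length and expression level, which argues against such a bias. The ribosomal protein median lay at percentile 74.8 of matched lists from outside the list, so genes nearest to it in length and expression fell alike. The matched genes were less abundant by 0.99 on the log2 scale, and the families they belong to were not examined. Short genes as a whole did not fall: the shortest of 10 length classes had a median log2 fold change of 0.38. A smaller share of germline RNA alone, which would raise somatic markers alike, cannot be told apart from other causes: neuronal and intestinal medians moved apart by 0.41 over libraries and differed by 0.49 over members (95% interval 0.14 to 0.83), but set against genes of like length and expression by −0.24 (−0.95 to 0.51). It stays open for the oocyte and germline genes, with developmental age, whether or not that axis captures it, and an effect of the RNAi itself.

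The second pattern is the rise of the intracellular pathogen response. With the same covariate its relative median was 2.19, but that fit extrapolates and cannot decide on timing along that axis, which stays open. The list lay at percentile 100 of lists matched on length and expression level, which argues against these properties as the source of its rise. A response of the worms to the RNAi treatment or to the bacteria is a hypothesis that the groups' design allows, and the labels' conflict over the food leaves a difference in bacteria open; neither was tested.

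The other pattern is the excess of genes at least 2-fold higher. A uniform background of genomic DNA or unspliced RNA in the RNAi libraries would give reads to nearly every gene, but 253 of 11310 protein-coding genes of at least 1000 bases had no count in any RNAi library (490 in the controls), a number between the bounds set for it. The lowest 5% of such genes leave room for a uniform background of at most 0.869 to 0.888 counts per kilobase, whereas the 2302 of them called at least 2-fold higher rose by a median of 165 to 245 per kilobase, at least 186 times as much; an uneven background was not tested. Over 3 other scalings the lowest ratio of higher to lower genes was 2.43, with DESeq2 size factors, so the excess was present with each of them. Its size depended on the scaling. All of these scalings were computed from the counts themselves, and more than 50% of the tested genes changed. The comparison therefore cannot exclude that scaling contributes to the excess, and this stays open. The change ran with expression level, from a median log2 fold change of 0.91 in the lowest of 10 expression classes to −0.49 in the highest, and a shift in which tissues or stages contribute RNA could also give this and stays untested.

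The 10 ways to split the 6 libraries 3 against 3 are too few for a share under 0.05. The real split called 8860 changed genes by edgeR and the highest of the others 0, with 18 to 321 genes at an unadjusted p under 0.05 on those; 1 split, the real one, was as large, and likewise 1 for the 4972 higher and 1 for the 3888 lower genes. For lists past camera the real value was 23 and the highest other 25, with 6 splits as large, and for classes 51 and 71, with 4 splits as large. Every other split mixes both groups on each side. The group difference then adds to the spread within the sides, which holds down gene calls, while part of it remains between them. The other splits therefore do not measure how often chance alone gives calls of genes, lists or classes.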
